A study of Arabidopsis thaliana with 24 samples.

How the data were processed

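Transcripts of whole Arabidopsis thaliana seedlings were measured on 24 Affymetrix ATH1 arrays, 3 for each of 8 groups. The groups cross genotype, light regime and treatment. The genotypes were wild-type Col-0 and ALC::TOC1, a line in which ethanol switches on TOC1, a repressor in the circadian clock. All seedlings were given MG132, an inhibitor of the proteasome. Per the submitters' processing notes, the deposited values are log2 expression values per probe set made with RMA in the Bioconductor package affy, with no version given. RMA corrects background, normalises by quantiles and summarises probes. The values ran from 2.165 to 13.7 and the array medians from 5.137 to 5.414, which is the range such log2 values take. Counts and depth do not apply to arrays, and the number of arrays limits the precision.

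Of 22810 probe sets, 64 controls were left out and 22746 were tested, with no filter on dim ones. The deposited annotation gave 1 gene name for 13513 probe sets, several for 503 and none for 8730. Of the 13513, 13436 matched a gene of the RefSeq annotation (TAIR10.1) and 77 did not. That made 13355 genes, 147 of them with more than 1 probe set. A gene with several probe sets was represented by the brightest. Unnamed probe sets were tested and counted, but only named ones could enter a gene list. TOC1, CCA1, LHY, PRR5, PRR7, PRR9, LUX and ELF4 had no named probe set and were not analysed here.

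All 24 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with a mean for each group. The fit had 16 residual degrees of freedom and 4.87 prior ones. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 in its comparison, two-sided. The 11 comparisons were the ethanol effect in each genotype and light regime, the genotype difference under mock in each light regime, and the light difference in wild type under mock. They also include the genotype by ethanol interaction (the ethanol effect in ALC::TOC1 minus that in wild type) in each light regime, its mean over both regimes and its difference between them. These comparisons, the test, the named-gene rule and 20 gene lists were fixed before the data were examined. The mean interaction was the main comparison. The labels do not say whether replicates were grown or treated separately, so each p-value measures the spread between samples only.

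The named genes were GI and the other clock genes listed above, the 6 largest rises and 6 largest falls among called probe sets with 1 gene name, and up to 3 members with the smallest adjusted p of each list with at least 3 called members. In comparisons of 2 groups, the largest rises and falls were taken only from probe sets whose 3 arrays of one group did not overlap the 3 of the other, as a share of 0.1 of probe sets would by chance. A few further genes are named as examples of a list, chosen after their values were seen.

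Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, 1 probe set per gene. The p-values were adjusted over 22 lists and 11 comparisons. Comparisons outside these 11 were adjusted as a separate family. They are the genotype differences under ethanol and the differences between light regimes described below. Of the 20 planned lists, with 251 entries, 33 entries had a named probe set. The 6 lists with at least 3 measured members were photosynthesis, ethanol and acetate metabolism, heat shock, mitochondrial stress and detoxification, cold response, and auxin and growth. Another 16 lists, with 302 of 323 entries measured, were not planned. They were composed from the gene names after the data and the probe annotation were seen. They were core hypoxia, small heat shock proteins and co-chaperones, unfolded protein response, tau glutathione transferases and redox, cold and dehydration, nuclear photosynthesis, clock-associated, expansins and xyloglucan transferases, auxin response, autophagy, calcium and rapid stress, sugar transporters and starch, root hair markers, mitosis markers, mitochondrion-encoded and plastid-encoded genes. The remaining planned lists, root and dividing cell markers among them, had too few named probe sets and were not analysed here.

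RNA quality was read from control probe sets for the 3' and 5' ends of GAPDH, actin and ubiquitin, and compared by exact permutation tests. Alternatives tried were a filter on dim probe sets, quantile normalisation again, centring each array on its median, eBayes with trend and robust settings, a fit of the compared groups alone, array weights, the replicate number as a block, a 2-fold minimum, each replicate or array left out, and the genotype difference under ethanol in place of the interaction. Chosen after the data were seen were the GAPDH 3'/5' difference as a covariate, the 16 lists, and the differences between light regimes of the wild-type ethanol effect and of the mock genotype difference. The fit was tested on simulated data with 100 probe sets changed 2-fold and 100 changed 4-fold. The simulated noise was normal, independent between probe sets and of equal spread in every array. For the mean interaction it called 98% of those changed 2-fold and 100% of those changed 4-fold, with 10 false calls. For the LL interaction it called 91% and 99%, with 7 false calls. The real arrays differ in spread (residual SD 0.1052 to 0.1989), so these shares may be too high for them. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.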

Results

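The data are 24 arrays of 13-day-old seedlings harvested at ZT1, that is 1 h after lights-on or, in constant light, after the time at which lights would have come on. After 12 days of 12:12 light-dark cycles, seedlings spent 1 day in constant light (LL) or stayed in light-dark cycles (LD). They then received a mock treatment or 2.5% ethanol, submerged for 3 h in MS medium with MG132, stated in the labels as 20 mM. With 2 genotypes, this gave 8 groups of 3 arrays. The arrays of a group correlated at 0.9885 to 0.9968. Of the variance, 35% lay along a first principal component that separated LL from LD arrays, and 23% along a second that separated mock from ethanol arrays. The GAPDH 3'/5' difference, which rises as RNA degrades, was 1.45 ± 0.152 log2 (SD, n = 3) in wild-type LL mock arrays and 0.834 to 1.13 in the means of the other groups. No difference in such ratios passed an exact permutation test in 21 two-sided tests, where 3 arrays against 3 allow no p under 0.1 (lowest adjusted p 0.2625). Values below are log2 differences ± SE from limma, with 3 arrays per group. Whether group means under 4 log2 units lie above background was not tested, so a difference that involves one has an uncertain size. This holds for AT1G49000 in wild type in LD, for AT4G25790 in wild type in LL, and for AT5G45630 (LL), AT1G52560, ATHSP22.0 and CYP71B23 (LD) in ALC::TOC1. It also holds for AT3G48640 between genotypes, AT3G15310 between light regimes, and the interactions of AT5G55800, AT4G25780, SBTI1.1, AT1G50060, AT1G50180 and EXPA8.

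**Figure D1:**
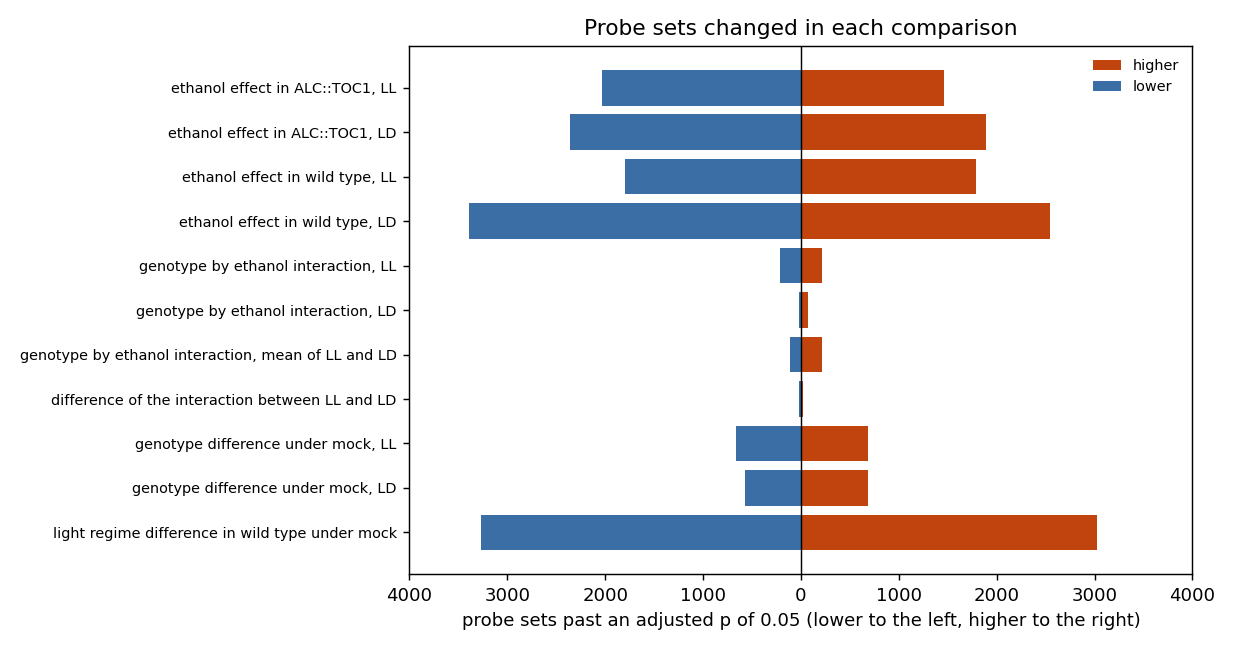
Number of probe sets higher and lower at an adjusted p under 0.05 in each comparison, from 3 arrays per group. The plain ethanol effects and the light difference hold 3495 to 6294 probe sets each, and the interactions 43 to 427. Which genotype has more ethanol calls changes when only the compared groups are fitted.

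Wild-type seedlings show what ethanol did without the transgene. In LL, GSTU25, a glutathione transferase of the tau class, rose by 2.52 ± 0.38 (adjusted p 0.000115). EXLA2, an expansin-like protein, rose by 1.93 ± 0.17 and GI (GIGANTEA, a clock-associated protein) by 0.94 ± 0.19 (adjusted p 0.00191). The other largest rises of named genes, of 2.01 to 2.57, were those of AT1G19025, AT1G43910, AT1G54050, AT2G34020 and AT3G19240, and of CML37 among the calcium genes. A dimmer probe set of AT1G19025 gave 0.52 (adjusted p 0.137). Among named genes, the falls were led by AT2G43620 at −3.12 ± 0.48, AT2G17740 at −3 ± 0.55 and AT1G72060 at −2.9 ± 0.37. AT2G17740 missed the threshold when only the compared groups were fitted (adjusted p 0.0563). In all, 1792 probe sets rose and 1799 fell in LL. The 3'/5' differences moved with ethanol here by −0.43 (GAPDH), −0.41 (actin) and −0.155 (ubiquitin), each at an exact permutation p of 0.1, the smallest possible. Of 3591 calls, the count became 2130 with the GAPDH 3'/5' covariate and 2183 with only the compared groups fitted.

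In LD, ethanol raised small heat shock proteins in wild type: AT1G53540 by 2.9 ± 0.41 (adjusted p 2.72e-05) and AT5G37670 by 2.5 ± 0.42. Their co-chaperone AT5G48570, an FK506-binding protein, rose by 2.93 ± 0.45 and EXLA2 by 2.64 ± 0.17. AT2G23110 rose by 3 ± 0.42 and GI by 1.07 ± 0.19 (adjusted p 0.000293). The largest falls of named genes were AT2G43620 at −3.72 ± 0.48, AT3G47380 at −3.54 ± 0.29 and AT1G49000 at −3.24. ATPC1, a chloroplast ATP synthase subunit, fell by 0.91 ± 0.13. Probe sets that rose numbered 2541, and 3391 fell. Array medians changed by −0.12 in this comparison. With each array centred on its median, the share of called probe sets that were higher went from 42.8% to 63.8%. Across genes, which are not independent replicates, the LL and LD ethanol effects of wild type correlated with r = 0.594 (rho 0.442), with 923 shared rises and 960 shared falls, while 72 probe sets were called in opposite directions.

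By list, 14 of 17 small heat shock proteins and co-chaperones rose with ethanol in wild type in LD (camera adjusted p 1.56e-08, adjusted p = 0.255 with an estimated correlation), and 7 rose in LL (6.14e-05, adjusted p = 0.388 with an estimated correlation). With the GAPDH 3'/5' covariate, the latter number was 2, and AT1G54050 missed the threshold (1.17, adjusted p 0.0622). The wild-type LL mock group has the highest mean GAPDH 3'/5' difference. Of 23 expansins and xyloglucan transferases, 8 rose and 1 fell in LL (0.0434, adjusted p = 0.307 with an estimated correlation), and 8 rose and 2 fell in LD (0.015, adjusted p = 0.253 with an estimated correlation). Among 22 tau glutathione transferases and redox genes, 9 rose and 1 fell in LL (0.00255, adjusted p = 0.193 with an estimated correlation). The number that rose was 5 with the covariate, and also 5 without wild-type LL mock replicate 2 or wild-type LL ethanol replicate 2.

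Of 24 nuclear photosynthesis genes, 13 fell with ethanol in wild type in LD (3.74e-05, adjusted p = 0.477 with an estimated correlation), ATPC1 and SBPASE, a Calvin cycle enzyme (−0.71 ± 0.16), among them. The number was 7 without wild-type LD mock replicate 2 or ethanol replicate 1, and 13 with the GAPDH 3'/5' covariate. That ethanol array had the highest actin (5.094) and ubiquitin (1.389) 3'/5' differences of the 24 arrays and a GAPDH difference of 1.575, against 0.8575 and 0.9509 in replicates 2 and 3 of its group. In LL, 3 of them fell (0.0105, adjusted p = 0.666 with an estimated correlation), and 1 to 5 with single arrays left out: 1 without mock replicate 3, ethanol replicate 1 or ethanol replicate 2, and 5 without ethanol replicate 3. Of 16 mitochondrion-encoded genes, 8 rose in LD (0.000639, adjusted p = 0.253 with an estimated correlation). That number was 5 without mock replicate 1, 4 without mock replicate 2 or 3, 3 without ethanol replicate 2 and 4 without ethanol replicate 3. Of 10 autophagy genes 5 rose in LD (0.00635, adjusted p = 0.39 with an estimated correlation). Of 25 core hypoxia genes 9 rose and 1 fell in LD (0.00351, adjusted p = 0.511 with an estimated correlation).

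In ALC::TOC1 seedlings the same ethanol treatment raised AT5G55800 by 6.36 ± 0.17 in LL (adjusted p 2.61e-16) and by 4.77 ± 0.17 in LD. SBTI1.1, a subtilisin-type serine protease, rose by 3.9 ± 0.18 in LL and 3.63 ± 0.18 in LD. AT4G25780 rose by 3.52 ± 0.22 in LL, AT5G45630 by 3.34 ± 0.39 and AT5G67020 by 3.25 ± 0.16. In LD, small heat shock proteins stood among the largest rises, with AT5G37670 at 3.97 ± 0.42, AT1G52560 at 3.94 ± 0.57 and ATHSP22.0 at 3.91 ± 0.44. The falls were led by AT2G43620, at −3.98 ± 0.48 in LL and −4.28 ± 0.48 in LD, and CYP71B23, a cytochrome P450, fell by 3.69 ± 0.28 in LD. GI was not called, at 0.5 ± 0.19 in LL (adjusted p 0.0913) and 0.17 ± 0.19 in LD (adjusted p 0.617). In LL it passed after quantile normalisation (0.0487), with array weights (0.0421) and with only the compared groups fitted (0.0077). In LL 1466 probe sets rose and 2029 fell, and in LD 1891 rose and 2364 fell. Array medians changed by −0.1 with ethanol in LL. Median centring moved the share of calls that were higher from 41.9% to 64.1% in LL and from 44.4% to 56.9% in LD.

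Much of this response was shared with wild type. In LD the ethanol effects of the genotypes correlated across genes with r = 0.748 (rho 0.614). There were 1274 shared rises and 1563 shared falls, where chance gives 211 and 352. In LL r was 0.588 (rho 0.457), with 621 shared rises and 898 shared falls. By list, 13 of 17 small heat shock proteins and co-chaperones rose in ALC::TOC1 in LD (2.02e-09, adjusted p = 0.253 with an estimated correlation), and 1 rose and 1 fell in LL. Of the expansins and xyloglucan transferases 8 rose in LD (0.00702, adjusted p = 0.221 with an estimated correlation) and 6 in LL (0.0455, adjusted p = 0.307 with an estimated correlation). Of 19 sugar transporter and starch genes 7 rose in LD (0.00255, adjusted p = 0.193 with an estimated correlation). Of the core hypoxia genes 6 rose and 1 fell in LL (0.0103, adjusted p = 0.54 with an estimated correlation).

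The main comparison asks where the ethanol response differed between ALC::TOC1 and wild type. No group carried the ethanol switch without TOC1, the TOC1 level was not analysed, and the genotypes already differed under mock. An effect of TOC1 therefore cannot be told apart here from other differences between the lines. Averaged over LL and LD, the interaction was 5.46 ± 0.17 for AT5G55800 (adjusted p 5.94e-15), 3.86 ± 0.22 for AT4G25780 and 3.71 ± 0.18 for SBTI1.1. In the 6 ALC::TOC1 ethanol arrays AT5G55800 lay between 7.72 and 9.89 log2 units, and in the other 18 arrays between 3.02 and 3.73. The lowest values of the arrays were 2.165 to 2.429 and their medians 5.137 to 5.414. SBTI1.1 lay between 7.54 and 8.46 against 3.47 to 4.66, and AT4G25780 between 7.32 and 7.98 against 3.74 to 5.64. AT1G45160 (2.26 ± 0.13) and AT5G67020 (2.29 ± 0.16) were likewise higher in every ALC::TOC1 ethanol array than in any other. AT1G80130, at 2.41 ± 0.27 (adjusted p 1.2e-05), differed in kind. It fell with ethanol in wild type, by 1.45 ± 0.27 in LL and 2.78 ± 0.27 in LD, and passed no test for an ethanol effect in ALC::TOC1.

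**Figure D2:**
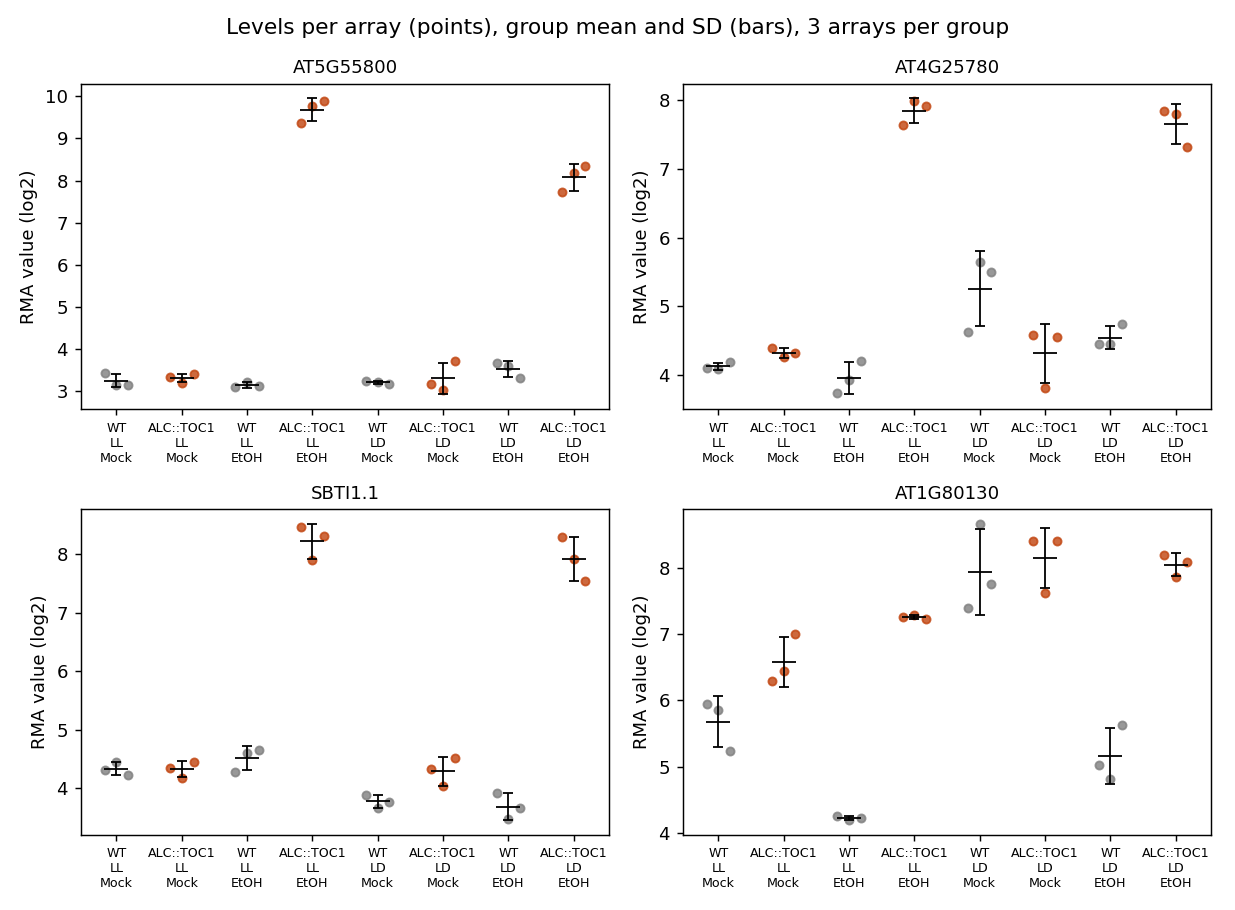
Log2 expression of the named genes with the largest mean interaction in each of the 24 arrays, by group of 3. AT5G55800 lies above 7 in all 6 ALC::TOC1 ethanol arrays and below 4 in the other 18.

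The negative side of the mean interaction held smaller values. AT5G55050 stood at −1.25 ± 0.26 (adjusted p 0.0146) and AT1G50060 at −0.93 (adjusted p 0.017). The mean of AT5G55050 came from LL, with −2.44 there and −0.06 in LD (adjusted p 0.975). AT1G50060 stood at −1.88 in LL, and in LD its 12 arrays lay at 3.05 to 3.66, not shown to be above background, so an LD interaction could not be read there. GI did not pass, at −0.67 ± 0.19 (adjusted p 0.0976), though it did without wild-type LD mock replicate 3 (0.0497) and with array weights (0.0409). In all, 218 probe sets had a positive mean interaction and 115 a negative one, and 72 of the 333 differed at least 2-fold. The count was 514 without wild-type LL ethanol replicate 3. Of the 24 nuclear photosynthesis genes 0 passed by limma (15 were positive at an unadjusted p under 0.05), but as a set they lay higher than other genes (camera adjusted p 1.44e-11, adjusted p = 0.322 with an estimated correlation). Fry, which tests the set against no change, gave an adjusted p of 0.0541. RNA quality was not excluded for this set, as wild-type LD ethanol replicate 1 and the wild-type LL mock group, with high 3'/5' differences, enter the comparison.

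Taken by light regime, the interaction in LL was 6.47 ± 0.24 for AT5G55800, 3.72 ± 0.25 for SBTI1.1, 3.69 ± 0.31 for AT4G25780 and 3.3 ± 0.23 for AT5G67020. In LD it was 4.46 ± 0.24 for AT5G55800, 4.04 ± 0.31 for AT4G25780 and 3.71 ± 0.25 for SBTI1.1. GPDHp, a plastid glycerol-3-phosphate dehydrogenase, stood at 2.09 ± 0.22 in LD. The most negative named genes were AT5G55050 at −2.44 ± 0.37 in LL (adjusted p 0.000696) and, of those kept in every left-out array, AT1G23460 at −1.36 in LD. AT1G50180 (−1.32 in LD) lay at 3.18 in wild type and 3.21 in ALC::TOC1 under ethanol, so its value rests on the mock arrays (3.49 and 4.84). AT1G23460 in LD likewise differed mainly under mock, at 5.86 in wild type and 7.06 in ALC::TOC1, against 7.13 and 6.98 under ethanol. Its value thus rests on the mock arrays too. AT1G23460 missed the threshold when only the compared groups were fitted (adjusted p 0.0776). GI did not pass in either regime, at −0.44 (adjusted p 0.487) and −0.9 (adjusted p 0.163). In LL 215 probe sets were positive and 212 negative, and in LD 77 and 17. Of the 215, 165 also rose in ALC::TOC1 and 68 fell in wild type. Of the 212, 102 fell in ALC::TOC1 and 121 rose in wild type. Of the 17, 14 differed between the genotypes under mock in the opposite direction.

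The interactions in LL and LD shared 46 positive probe sets, where chance gives 0.728, and 1 negative one, where chance gives 0.158. Across genes the interactions correlated little (r = 0.0716, rho −0.0139). The LL count of 427 was 275 without ALC::TOC1 LL mock replicate 2, 277 without its replicate 3, 242, 251 and 733 without wild-type LL ethanol replicates 1, 2 and 3, and 723 and 193 without ALC::TOC1 LL ethanol replicates 1 and 3. The LD count of 94 was 60 without wild-type LD mock replicate 3, 58 without ALC::TOC1 LD mock replicate 2, 374 without wild-type LD ethanol replicate 3, and 49, 59 and 337 without ALC::TOC1 LD ethanol replicates 1, 2 and 3. After median centring, 66.9% of the LL calls and 71.9% of the LD calls were positive, against 50.4% and 81.9% as deposited.

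**Figure D3:**
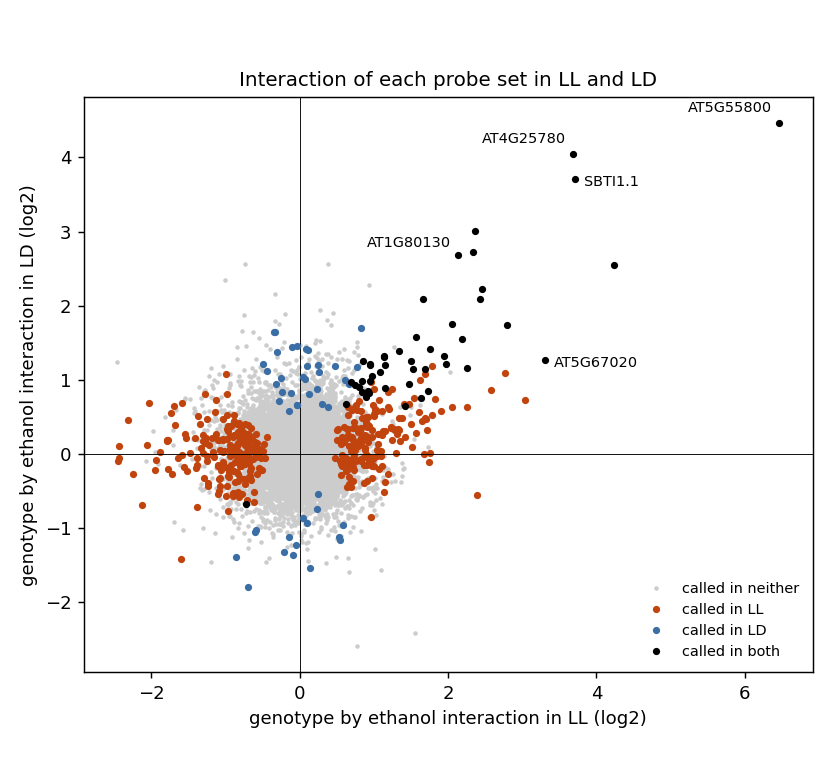
Interaction (log2) in LL on the x axis and in LD on the y axis, a point per probe set. AT5G55800, AT4G25780 and SBTI1.1 lie far out on both axes, and the bulk of points shows little relation (r = 0.0716).

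Whether the interaction differed between light regimes was tested directly. It was larger in LL than in LD for AT5G67020, by 2.03 ± 0.33, and for AT5G55800, by 2.01 ± 0.34 (adjusted p 0.0215 for each). For SBTI1.1 the difference was 0 ± 0.35 (adjusted p 0.998). In all 43 probe sets passed, 23 positive and 20 negative, against 3070 at an unadjusted p under 0.05. Without ALC::TOC1 LL ethanol replicate 3 the adjusted p of AT5G67020 and of AT5G55800 was 0.0521, and that of AT5G55800 was 0.0691 with the GAPDH 3'/5' covariate. Leaving out 1 array moved the count by over 1.5 times in 16 of 24 cases. In LL it was 67 without wild-type mock replicate 2, 24 and 22 without ALC::TOC1 mock replicates 2 and 3, 19 and 227 without wild-type ethanol replicates 2 and 3, and 393 and 2 without ALC::TOC1 ethanol replicates 1 and 3. In LD it was 18 without wild-type mock replicate 3, 21, 15 and 27 without ALC::TOC1 mock replicates 1, 2 and 3, 28 and 130 without wild-type ethanol replicates 2 and 3, and 21, 10 and 261 without ALC::TOC1 ethanol replicates 1, 2 and 3.

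Without inducer the genotypes already differed. AT5G18840 was lower in ALC::TOC1 under mock, by −2.96 ± 0.3 in LL (adjusted p 4.94e-06) and −3.28 ± 0.3 in LD (adjusted p 7.07e-07). AT3G48640 was lower too, at −2.72 ± 0.39 in LL and −2.5 ± 0.39 in LD. In LL the pseudogene AT5G28430 was higher by 1.49 ± 0.21 and EXLA2 by 1.07 ± 0.17. In LD AT2G25510 was higher by 3.01 ± 0.59 and AT5G16980 by 2.26 ± 0.2. GI differed by 0.25 ± 0.19 in LL (adjusted p 0.52) and 0.22 ± 0.19 in LD (adjusted p 0.618). In LL 689 probe sets were higher and 666 lower, and in LD 690 and 568. Both regimes shared 165 higher and 156 lower probe sets, where chance gives 20.9 and 16.6.

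Those LL calls, 1355 in all, were 423 without wild-type LL mock replicate 1, 845 without its replicate 2, and 789 and 645 without ALC::TOC1 LL mock replicates 1 and 3. In LD 1258 calls became 658 without wild-type LD mock replicate 3, and 728 and 775 without ALC::TOC1 LD mock replicates 1 and 3. With the GAPDH 3'/5' difference, whose group mean was highest in wild-type LL mock, as a covariate, 327 LL calls were left. Across genes, the mock difference and the interaction, which share arrays, correlated at −0.0455 in LL and −0.273 in LD, where simulated data with no effect gave −0.706 and −0.708. Real effects widen the spread, so these correlations are not directly comparable. The covariance was −0.00454 in LL and −0.0236 in LD, against −0.0221 simulated for each. In LD the shared mock arrays alone can thus give a covariance of this size.

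Genes known to respond to low oxygen separated the genotypes under mock in LL. Of 25 core hypoxia genes 11 were lower in ALC::TOC1 and 1, AT5G26200, was higher (camera adjusted p 1.46e-13, adjusted p = 0.21 with an estimated correlation). AT4G10270 was lower by −2.92 ± 0.42 (adjusted p 0.000301), AT5G66985 by −2.46 ± 0.28 (adjusted p 2.72e-05), AT3G10040 by −2.41 ± 0.4 and AT1G33055 by −2.09 ± 0.32. In LD 2 members were higher and 1 lower (0.175). The mean of the list was 7.36 ± 0.28 log2 units (SD, n = 3) in wild-type LL mock arrays, and 6.4 ± 0.18 in ALC::TOC1 LL, 6.62 ± 0.15 in wild-type LD and 6.75 ± 0.11 in ALC::TOC1 LD mock arrays. Under ethanol in LL it was 7.38 ± 0.53 in wild type and 6.79 ± 0.26 in ALC::TOC1. Without ALC::TOC1 LL mock replicate 1, 7 members were lower, and with the GAPDH 3'/5' covariate 9. AT5G26200 missed the threshold without wild-type LL mock replicate 1 (adjusted p 0.127), without ALC::TOC1 LL mock replicate 1 (0.0615) and with the covariate (0.0861).

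**Figure D4:**
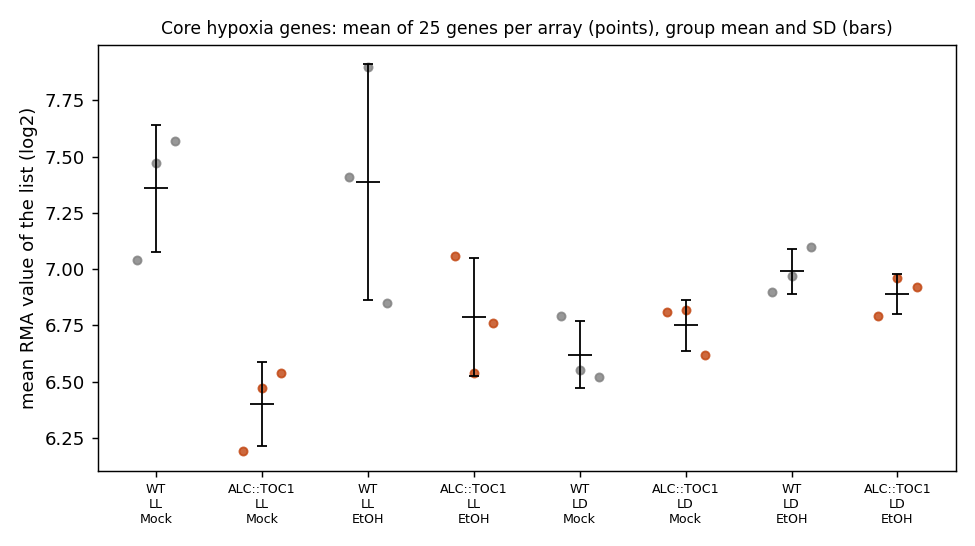
Mean log2 expression of the measured core hypoxia genes in each of the 24 arrays, with the mean of each group of 3. The wild-type LL mock arrays lie between 7.04 and 7.57 and the ALC::TOC1 LL mock arrays between 6.19 and 6.54.

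In wild type under mock, LL was set against LD. AT4G10270 and AT5G66985, both low-oxygen genes, were higher in LL by 4.7 ± 0.42 (adjusted p 9.24e-08) and 3.35 ± 0.28. AT4G11190 and AT1G52070 were higher by 2.92 and 2.85. GI was lower in LL by −1.38 ± 0.19 (adjusted p 1.94e-05) and COR15A, a cold-regulated chloroplast protein, by −2.68. AT5G51440, a mitochondrial small heat shock protein, was lower by −2.82 ± 0.26, and the pseudogene AT3G15310 by −3.4 ± 0.29. In all 3029 probe sets were higher and 3265 lower in LL. The GAPDH 3'/5' difference was 0.362 higher in the LL arrays of this comparison (exact p 0.1, the smallest possible).

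By list, 11 of 17 small heat shock proteins and co-chaperones were lower in LL (4.59e-06, adjusted p = 0.347 with an estimated correlation), 7 of 12 mitosis markers were higher (3.48e-06, adjusted p = 0.253 with an estimated correlation) and 11 of 23 expansins and xyloglucan transferases were higher (3.74e-05, adjusted p = 0.148 with an estimated correlation). AUR1, an Aurora kinase of dividing cells, was higher by 1.55 ± 0.15 and the histone gene HTB2 by 1.72. Of the core hypoxia genes 11 were higher and 2 lower in LL (0.000741, adjusted p = 0.448 with an estimated correlation). Of 69 plastid-encoded genes 12 were higher (3.47e-06, adjusted p = 0.583 with an estimated correlation), a number that was 6 without wild-type LD mock replicate 1, 7 without its replicate 3, and 4 with the GAPDH 3'/5' covariate. Of 11 clock-associated genes 1 was higher (AT4G33980, 1.5 ± 0.18) and 3 lower. The lower number was 5 without wild-type LL mock replicate 3.

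**Figure D5:**
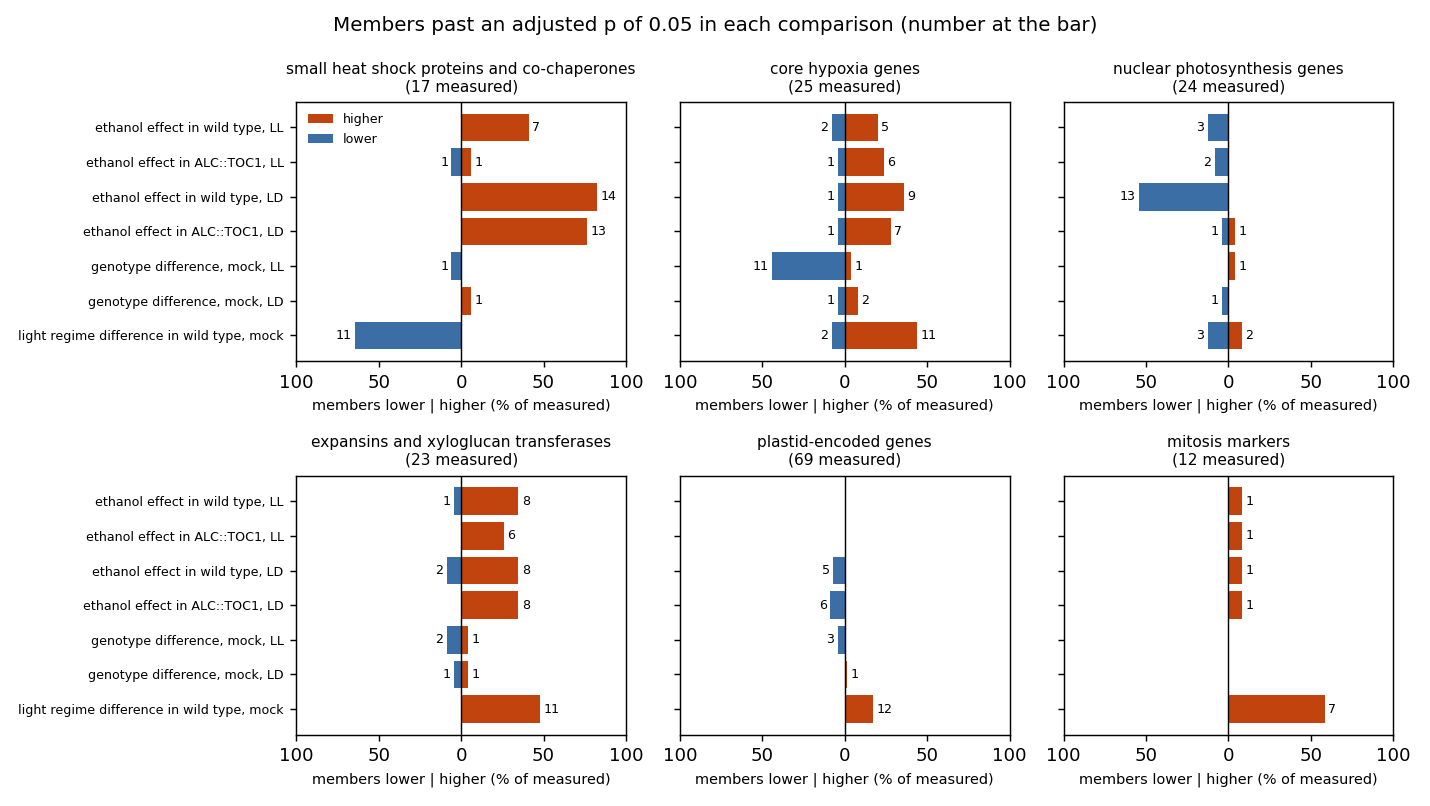
Number of members of selected gene lists higher and lower at an adjusted p under 0.05, by comparison. Small heat shock proteins rise with ethanol in LD in both genotypes, 14 and 13 of 17 members, and core hypoxia genes are lower in ALC::TOC1 under mock in LL, 11 of 25.

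The planned lists with at least 3 named members were small. Of 3 heat shock genes all 3 rose with ethanol in LD, in wild type (0.00189, adjusted p = 0.255 with an estimated correlation) and in ALC::TOC1 (6.14e-05, adjusted p = 0.193 with an estimated correlation), and adjusted over the list alone the counts were also 3. In wild type in LL 1 of them rose, and 2 adjusted over the list alone. Of 4 mitochondrial stress genes 3 rose in wild type in LL (0.00227, adjusted p = 0.193 with an estimated correlation) and 3 in ALC::TOC1 in LD (0.00065, adjusted p = 0.193 with an estimated correlation), with 3 in each adjusted over the list alone. GSTU25 is 1 of them, and AT2G21640, at 2.16 in ALC::TOC1 in LD, is another. In wild type in LL AT2G21640 missed the threshold without mock replicate 2 (adjusted p 0.0587) and with the GAPDH 3'/5' covariate (adjusted p 0.336). Of 3 ethanol and acetate metabolism genes, PDC2 (pyruvate decarboxylase, 0.95 ± 0.15) and 1 more rose in ALC::TOC1 in LL and 2 in wild type in LD, with 2 in each adjusted over the list alone.

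Of the 3 photosynthesis genes planned, RCA (Rubisco activase, −0.32 ± 0.09) and LHCB4.2 (a light-harvesting protein, −0.89 ± 0.32) fell in wild type in LD, with 2 adjusted over the list alone. RCA missed the threshold without wild-type LD mock replicate 2 (adjusted p 0.0871) or ethanol replicate 1 (0.0587) and after median centring (0.0917) or quantile normalisation (0.0521). LHCB4.2 missed it without mock replicate 2 or 3 or ethanol replicate 1 or 2 (0.107 to 0.229), and after median centring (0.0564). Of 3 cold response genes 1 fell in ALC::TOC1 in LL and 1 in wild type in LD, with 1 in each adjusted over the list alone. The latter, COR15A (−1.52), missed the threshold without wild-type LD ethanol replicate 2 (adjusted p 0.0796). Of 3 auxin and growth genes 1 rose and 1 fell in wild type in LL and 2 fell in LD, with equal counts adjusted over the list alone. In the mean interaction 1 of them, EXPA8 (0.84 ± 0.19), was positive, but missed the threshold without ALC::TOC1 LD ethanol replicate 2 (adjusted p 0.0516). In the LL interaction, 1 planned list member passed, the heat shock gene AT1G53540, with −2.32 ± 0.59 (adjusted p 0.0439). It missed the threshold (adjusted p 0.0712 to 0.147) without LL replicates 1 or 2 of wild-type mock or wild-type ethanol, 2 or 3 of ALC::TOC1 mock, and 1 or 3 of ALC::TOC1 ethanol. With the GAPDH 3'/5' covariate its adjusted p was 0.211.

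Of 13 unfolded protein response genes 5 rose and 2 fell with ethanol in wild type in LD, with a median of −0.06 and a mean of 0.13. Of 9 cold and dehydration genes 4 were higher and 2 lower in LL than in LD in wild type under mock, with a median of 0.44 and a mean of −0.17. Of 13 auxin response genes 2 rose with ethanol in wild type in LL. Of 15 calcium and rapid stress genes 5 rose and 4 fell with ethanol in ALC::TOC1 in LD, with a median of −0.21 although camera ranked them upward (0.973). The number that rose was 3 without mock replicate 3 or ethanol replicate 1. In wild type in LL 2 of 4 root hair markers rose (0.0187, adjusted p = 0.307 with an estimated correlation), EXPA7 by 0.86 ± 0.15 and AT4G25790 by 1.07 ± 0.22. AT4G25790 missed the threshold when only the compared groups were fitted (adjusted p 0.0721). Over all lists and comparisons, camera called 65 of 242 tests at the preset correlation and 0 with an estimated one (34 at an unadjusted p under 0.05), and fry called 68.

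Several list counts fell by over 1.5 times when a replicate number was left out of every group, which leaves 2 arrays per group. For ethanol in wild type in LD, without replicate 1 there were 2 autophagy and 7 nuclear photosynthesis genes. Without replicate 2 there were 9 small heat shock proteins and co-chaperones, 3 nuclear photosynthesis, 0 mitochondrion-encoded and 2 unfolded protein response genes, and without replicate 3 there were 2 mitochondrion-encoded genes. In wild type in LL, without replicates 1 and 2 the tau glutathione transferases and redox genes that rose were 5 and 3, and the nuclear photosynthesis genes that fell were 1 and 0. The mitochondrial stress genes that rose there were 1 without replicate 2. In ALC::TOC1, core hypoxia genes that rose in LL were 3 without replicate 1, and sugar transporter and starch genes that rose in LD were 3 without replicate 2. The calcium genes that rose in LD were 3, 2 and 3 without replicates 1, 2 and 3. Between genotypes under mock in LL, 4 and 6 core hypoxia genes were lower without replicates 1 and 2. Between light regimes, 7 core hypoxia genes and 7 expansins and xyloglucan transferases were higher without replicate 2, 7 plastid-encoded genes without replicate 3, and 2 cold and dehydration genes without replicate 2 or 3.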

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

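All results here were picked because an effect differed between groups by a direct test of the difference. The tests chosen only after the results were seen were those with the GAPDH 3'/5' covariate, the comparisons of the wild-type ethanol effect and of the mock genotype difference between light regimes, the tests of replicate spread, of the mock samples and of single LD arrays in the first pattern, and those of the wild-type and ALC::TOC1 levels in the second. The patterns themselves were found in the data on which they were then tested.

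The ethanol effect differed between genotypes for 427 probe sets in LL and 94 in LD, and that interaction differed between LL and LD for 43. Of the 43, 23 were positive and 20 negative, and those named here are the 6 largest on each side with 1 gene name. The positive ones were AT5G67020 (2.03), AT5G55800 (2.01), CML41 (1.81), AT5G25240 (1.73), AT3G62780 (1.72) and AT3G53950 (1.67). The negative ones were AT1G05205 (−1.36), AT5G01260 (−1.8), AT3G48460 (−1.86), AT1G50060 (−1.92), AT5G52810 (−1.98) and AT5G62360 (−2.07). All 12 had adjusted p values from 0.0215 to 0.0496. Without ALC::TOC1 LL ethanol replicate 3, all of them but CML41 missed the threshold, and 2 probe sets passed in place of 43. For AT1G50060, the LD arrays lay at 3.05 to 3.66, not shown to be above background, so its difference rests on LL alone. AT5G55800, AT3G62780 and CML41 also had group means under 4, so the size of their differences is uncertain. CML41 missed it without wild-type LD mock replicate 3 (0.0539), ALC::TOC1 LD mock replicate 2 (0.0523) or ALC::TOC1 LD ethanol replicate 2 (0.0581). AT5G62360 also missed it without ALC::TOC1 LD ethanol replicate 2 (0.0522). AT5G01260 also missed it without wild-type LL ethanol replicate 2 (0.0522), ALC::TOC1 LD mock replicate 2 (0.0524) or ALC::TOC1 LD ethanol replicate 2 (0.0559). AT3G62780, AT3G53950, AT5G52810, AT1G05205 and AT1G50060 missed it in 10, 12, 15, 17 and 18 of the 24 cases of 1 array left out, with values up to 0.131.

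The wild-type ethanol effect differed between LL and LD for 1348 probe sets. The genotype difference under mock differed between LL and LD for 118, and the low-oxygen genes AT5G66985 (−2.28 ± 0.4), AT3G10040 (−2.93 ± 0.56) and AT4G10270 (−3.22 ± 0.59) were among them. These comparisons were not recomputed with arrays left out.

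The first pattern is that the interaction passed for more probe sets in LL than in LD, 427 against 94. Without replicate 3 in every group it turned around, with 166 in LL and 390 in LD. The residual SD of LD over LL arrays was 0.994. This ratio is no test of the gap, as both interactions share 1 estimate of the spread (median SE 0.175 in each). The tables argue against mock differences (7.49% of the LL calls had a larger genotype difference under mock than under ethanol, 28.7% in LD). With the GAPDH 3'/5' covariate the counts were 354 against 105, so the gap stayed. The slope of that covariate rests on the spread within groups of 3 arrays, so RNA quality was not excluded. With it, 11 probe sets passed for the difference between regimes, against 43 without. Without ALC::TOC1 LL ethanol replicate 3, the least favourable LL array, there were 193 LL calls, narrowly above double the LD count, the bound set for this test. The state of single LD arrays stays open too. The LD count was 374 without wild-type LD ethanol replicate 3 and 337 without ALC::TOC1 LD ethanol replicate 3, against 427 in LL with all arrays. The LL count rose too, to 733 without wild-type LL ethanol replicate 3 and 723 without ALC::TOC1 LL ethanol replicate 1. An LD count with 1 array left out is thus not like for like with the full LL count, and does not settle whether a single LD array accounts for the gap. A light-dependent response of the transgene is a candidate explanation that these values do not separate from RNA quality or single arrays.

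The second pattern is that low-oxygen genes were lower in ALC::TOC1 than in wild type under mock in LL, 11 of 25. The tables argue against a single array, since 7 were lower without ALC::TOC1 LL mock replicate 1, the lowest number with any 1 of the 6 left out. With the GAPDH 3'/5' covariate 9 were lower. Its slope rests on the spread within groups of 3 arrays, so RNA quality was not excluded. Left out by replicate number in every group, replicate 1 left 4 and replicate 2 left 6. The wild-type LL mock mean of the list exceeded that of each other mock group by at least 0.61, and the ALC::TOC1 LL mock mean lay below each by at least 0.22, both more than the larger SD. So a high level in the one and a low level in the other both remain. The high level was not particular to mock, as the mean in wild type in LL was 7.36 ± 0.28 under mock and 7.38 ± 0.53 under ethanol. Whether the submerged wild-type LL seedlings may have met less oxygen, or the genotypes differ in their response, stays open, and the labels record no oxygen level.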

How the results depend on the processing

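Tests chosen after the data were seen were those with the GAPDH 3'/5' covariate. Of 318 gene values by comparison, 194 stayed on their side of the threshold in every setting run. Of values called in the main fit or in the setting, 0 turned direction, and uncalled ones were not checked for this. Calls were lost by 12 with median centring, 7 with quantile normalisation, 7 with trend and robust settings, 4 with the replicate block, 31 with only the compared groups fitted and 36 with the covariate. All plain ethanol effects and the light difference stayed within 1.5 times of their counts when any single array was left out. For counts that moved further, the cause was not tested, except that a 2-fold minimum lowers counts by construction. With a 2-fold minimum the counts were 558 and 718 for ethanol in ALC::TOC1 (LL, LD), 532 and 920 in wild type, 178, 61 and 72 for the interaction (LL, LD, mean), 228 and 253 for genotype under mock and 1103 for light. With array weights they were 7118 for ethanol in ALC::TOC1 in LD, 1424, 542 and 1017 for the interaction, 1025 for its difference between regimes, and 2085 and 3960 for genotype under mock. With only the compared groups fitted they were 2183 for ethanol in wild type in LL, 268 and 45 for the interaction and 597 for genotype under mock in LL. That fit gave ALC::TOC1 more ethanol calls than wild type, 3590 against 2183 in LL and 4745 against 4059 in LD. In the main fit wild type had more, 3591 against 3495 in LL and 5932 against 4255 in LD. Mean residual SD was 0.161 to 0.183 in wild-type groups and 0.125 to 0.146 in ALC::TOC1 groups. With the covariate the counts were 2130 for ethanol in wild type in LL, 11 for the difference of the interaction and 327 for genotype under mock in LL. That difference gave 18 with dim probe sets removed and 68 with median centring. The genotype difference under ethanol alone gave 5583 in LL and 3260 in LD. Camera with an estimated correlation called 0 of the list tests, against 65 at the preset one, 68 by fry, and 34 at an unadjusted p under 0.05.

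With replicates left out, singly or by number in every group, counts ran from 1582 to 3428 and from 1798 to 4066 for ethanol in ALC::TOC1 (LL, LD), and from 1528 to 3258 and 2854 to 5930 in wild type. They ran from 85 to 733, 18 to 390 and 97 to 514 for the interaction (LL, LD, mean), and from 0 to 393 for its difference. For genotype under mock they ran from 131 to 2006 and 322 to 1370, and for light from 3754 to 5973. As a block, the replicate number moved no count by over 1.5 times. In a check of pairing, 4 of 21 pairs of arrays with the same number correlated above 0.1 (range −0.399 to 0.488), and in 0 of 7 comparisons did every pair. Ethanol in wild type in LL came closest, at 0.0997 to 0.488, so pairing is not excluded there. Elsewhere arrays may share only a number. The TOC1 level was not recomputed in any setting, as no probe set carries that name. The replicate block within light regime was not run for the light comparison, which it would absorb. Genes near background limit small differences, and 3 arrays per group limit all of them.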

Other observations

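The comparison of the wild-type ethanol effect between light regimes, the tests of neighbouring genes and of AT5G loci and the look at exchanged genotypes were chosen only after the results were seen. The counts of other splits of the samples were planned.

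Set side by side under ethanol, the genotypes differed in nuclear photosynthesis genes. Of 24 nuclear photosynthesis genes, 14 were higher in ALC::TOC1 than in wild type under ethanol in LL (camera adjusted p 3.65e-06, adjusted p = 0.416 with an estimated correlation) and 14 in LD (4.43e-10, adjusted p = 0.375 with an estimated correlation). In LL, PGRL1B, of cyclic electron flow, was higher by 0.74 ± 0.11 (adjusted p 5.99e-05), and in LD SBPASE by 1.13 ± 0.16 (adjusted p 0.000108). Of 69 plastid-encoded genes 8 were lower in LL (0.000433, adjusted p = 0.667 with an estimated correlation) and 4 higher in LD (0.000824, adjusted p = 0.67 with an estimated correlation). Small heat shock proteins and co-chaperones were lower in LL, 10 of 17 (2.26e-06, adjusted p = 0.316 with an estimated correlation), Fes1A by −1.9 ± 0.23. Tau glutathione transferases and redox genes were lower in LL, 11 of 22 with 1 higher (0.000858, adjusted p = 0.144 with an estimated correlation), and GSTU25 was −1.56 ± 0.38 in LL and 2.82 ± 0.38 in LD. Of 11 clock-associated genes 5 were lower in LD (0.0376, adjusted p = 0.416 with an estimated correlation): AT4G33980 by −1.34 ± 0.18, COR27 by −1.24 ± 0.31, GI by −0.67 ± 0.19 (adjusted p 0.0226) and XCT by −0.55 ± 0.09 among them. Clock genes are not independent evidence between these genotypes, since the line was made to switch on a clock gene. These differences include those present under mock and were not recomputed with arrays left out. In LD they rest in part on wild-type ethanol replicate 1, with a GAPDH 3'/5' difference of 1.575 and the highest actin (5.094) and ubiquitin (1.389) ones of all arrays. The GAPDH group means were 1.13 in wild type and 0.834 in ALC::TOC1, so RNA quality was not excluded for the LD values.

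In wild type, the ethanol effect differed between LL and LD for some genes. GSTU25 rose in LL (2.52 ± 0.38) and was not called in LD (−0.29 ± 0.38), a difference of 2.8 ± 0.54 (adjusted p 0.00564), while XTH33, a cell wall enzyme (−2.18 ± 0.42), had the lower effect in LL. Of the core hypoxia genes 7 had a lower effect in LL (0.000433, adjusted p = 0.416 with an estimated correlation). The wild-type LL mock group, with the highest mean GAPDH 3'/5' difference (1.45), and wild-type LD ethanol replicate 1 (1.575) are part of this comparison.

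A hypothesis was that the genotype differences under mock shared by LL and LD lie near each other in gene order, as they would around an inserted or introgressed stretch. Of the 194 genes called the same way in both regimes, 29.9% had another among the 10 measured genes on either side. That share was reached by 0.2 of 1000 random sets, and was 24.2% for as many wild-type ethanol genes, so neither test showed clustering. A later test found AT5G loci among 62 of the 194 genes (32%), against 22.6% of the 13216 genes in gene order (Fisher's exact two-sided p times 5 tests 0.012). Of the 62, 33 were higher and 29 lower. For as many wild-type ethanol genes the number was 39. Linked differences between the lines on that chromosome may be the source, a hypothesis found after 2 tests that showed little.

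Other splits of the samples were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split alone reached its count (1 of 10) in each case. Every other split mixes arrays of the compared groups, so a difference between them widens the spread and lowers the count. The low counts of those splits therefore do not exclude chance. Real and highest other counts were 3495 and 0 for ethanol in ALC::TOC1 in LL, 4255 and 0 in LD, 3591 and 213 for wild type in LL, 5932 and 7 in LD, 1355 and 2 for genotype under mock in LL, 1258 and 7 in LD, and 6294 and 21 for light. For the interactions, genotype labels were exchanged at random within each light and treatment, for 100 splits with the real one included. As many calls as the real split, itself included, came from 12 in LL (427, highest other 4842), 11 in LD (94, highest other 1941), 5 for the mean (333, highest other 1430) and 7 for the difference (43, highest other 4559), so chance cannot be excluded by this count. Splits with several times the real count point to a structure of the samples. In all of the others that reached the real count, 11, 10, 4 and 6, genotypes were exchanged unequally between mock and ethanol arrays, which carries genotype differences into the interaction. Among splits with an equal exchange (42, 41, 27 and 16 in number, the real one included), the highest counts apart from the real one were 1, 0, 18 and 18. An equal exchange mixes the genotypes within groups, which widens the spread there and lowers the counts. So these low counts do not exclude chance either.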
